A study of Mus musculus with 12 samples.

How the data were processed

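The series holds 12 RNA sequencing libraries of cultured mouse islets, 3 for each of 4 conditions. Per the labels' protocols, messenger RNA libraries were made from total RNA with a strand-marking kit, and replicate 1 of each group was sequenced in batch 1 (4 libraries) and replicates 2 and 3 in batch 2 (8 libraries). The values used are the estimated counts per mouse transcript that the authors deposited, as whole numbers, not normalized. Kallisto and DESeq2 are named per the submitters' processing notes, without roles or versions, with GRCm38 as the genome build. The transcriptome release and the settings of the quantification, strand included, are not given in the sources used here, so counts of overlapping or antisense genes and of near-identical copies are uncertain. The 35 largest values are multiples of 10, since they carry 6 significant digits.

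Of 71524 transcripts in the deposited table, 69942 were matched by identifier to GENCODE M21 and summed to 22141 genes. The 1582 unmatched transcripts held 0.581% to 0.677% of the counts of a library and were tested apart. Counts were summed per gene and rounded to whole numbers. Column names were matched to the sample labels, which give the group and number of every library. Totals ran from 22216420 to 26110989 counts in batch 1 and from 35876350 to 50264695 in batch 2. Among 66 pairs of libraries, the lowest chi-squared per degree of freedom was 7.72, so no pair held the same library.

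Counts were filtered with edgeR's filterByExpr (15794 genes kept), scaled by TMM (factors 0.967 to 1.045) and fitted with edgeR 4.0.16 in R 4.3.3 by the robust quasi-likelihood method. The fit held all 12 libraries, with group and sequencing batch as terms, which left 7 residual degrees of freedom. The common biological coefficient of variation was 11.2%. There were 6 comparisons: palmitate against vehicle, palmitate with C3a against vehicle with C3a, C3a against no C3a within palmitate and within vehicle, the interaction, and the average of both C3a effects. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Standard errors were approximated from the fit as the absolute log2 fold change divided by the square root of the F statistic, and 95% intervals follow from them. All tests were two-sided. CPM values are counts scaled to library size.

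Gene lists were tested with limma 3.58.1 on log2 CPM (prior count 2) with the same model. Camera with a preset correlation of 0.01 compares a list with the other genes; camera with an estimated correlation and fry were run beside it, and adjustment was over the lists within a comparison. Lists with at least 5 measured members were tested, 32 of 33. The lists were beta cell identity; alpha, delta, PP, acinar, duct, endothelial, fibroblast and pericyte, macrophage, lymphocyte and Schwann cell markers; fatty acid oxidation and PPAR targets, cholesterol synthesis, fatty acid synthesis and desaturation; integrated stress response, ER chaperones and ERAD, heat shock, antioxidant and NRF2 targets, hypoxia and glycolysis, autophagy and lysosome; proapoptotic, antiapoptotic, NF-kB and inflammatory, interferon-stimulated, immediate early and cAMP-responsive, complement and proliferation genes; disallowed and dedifferentiation genes, insulin granule and exocytosis, oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins and dual-specificity phosphatases. The phosphatase list and Dusp26 came from memory of published work on this series. Members past the threshold were counted over all genes tested and with p adjusted over the list alone.

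Named genes were selected by a rule. Per comparison these were the 8 highest and 8 lowest log2 fold changes among called genes with at least 5 CPM in the higher group and 1 direction in all 3 same-numbered differences (this last condition not for the interaction and the average). Where fewer passed, genes of the fit with a replicate block were to fill the places, and then, up to 4 per direction, genes by smallest unadjusted p, named as not past the threshold. Up to 4 members of each list with the smallest p, and C3ar1, C3, Cfd, Dusp26, Ins1, Ins2 and Gcg, were added. Predicted genes and pseudogenes were counted and not named, except where a count was 5 or fewer. Some genes that the rule selects are not reported here. The groups, tests, lists, named-gene rule and first set of alternatives were chosen before the data were examined.

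The labels put all libraries numbered 1 in batch 1, and those numbered 2 and 3 carry a date-like tag that the 4 groups share. Deviations from the group mean of same-numbered libraries correlated at 0.395 or more across all 18 pairs (mean 0.575), and at 0.08 or more among the 12 pairs of batch 2 alone (mean 0.115). The numbers were therefore taken to pair the libraries, and the fit with the replicate number as a block was the other fit. Its coefficient of variation was 9.5%. The correlations over all 18 pairs include the difference between batches, since number 1 was batch 1. In batch 2 each group has 2 libraries, so numbers 2 and 3 give the same correlations and the 12 pairs are not independent.

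Alternatives tried were DESeq2 1.42.0, RLE size factors, no filter, a stricter filter of 1 CPM in 6 libraries, the replicate block, no batch term, an acinar score as a term, only the groups compared, transcripts tested one by one, and leaving out each library or replicate number in turn. A second set, chosen after seeing the data, was the replicate block with only the groups compared, leaving out the pair of palmitate libraries high in fibroblast genes, leaving out the pair of libraries with outlying hypoxia genes, a floor of 10 CPM for correlations in 2 definitions, and a correlation with no shared library. Correlations across genes were set against 50 simulations of unchanged groups, whose means differed by replicate number, and again, after seeing the data, with the variances of the replicate block fit.

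The tests were first run on simulated data with the real means and library sizes and 200 changed genes. For palmitate against vehicle (15601 genes), 18%, 60%, 74% and 90% of genes changed 1.25, 1.5, 2 and 4-fold were called, with 9 false calls among 15383 unchanged genes. For palmitate with C3a against palmitate (15636 genes) the shares were 24%, 50%, 66% and 88%, with 2 false calls. For the average (15633 genes) they were 50%, 72%, 86% and 92%, with 16 false calls. A list raised 1.5-fold was called in each simulation. Of the 31 other lists, 2, 0 and 0 were called with the preset correlation and 0 with the estimated one. The simulated genes varied independently of each other. These counts therefore do not show how the list tests behave where genes vary together, as in the hypoxia list (estimated correlation 0.742).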

Results

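The data are messenger RNA sequencing counts of 12 libraries from cultured mouse pancreatic islets, the endocrine clusters that hold the insulin-secreting beta cells. Islets came from male wild-type mice 10 to 12 weeks old and were cultured in lots of about 120. There were 4 conditions with 3 libraries each: vehicle, vehicle with C3a, palmitate, and palmitate with C3a. C3a is the small fragment released when complement component C3 is cleaved, and it acts through the receptor C3ar1. Palmitate is a saturated fatty acid that is widely used to stress beta cells in culture. The labels do not say whether the libraries of a group came from separate animals or cultures, so the p values measure the spread between these libraries. Dose and time of the treatments are not in the labels.

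Summed counts per library were 24408023, 49375454 and 42650415 for vehicle replicates 1, 2 and 3. They were 22216420, 43938156 and 45532091 for vehicle with C3a, 24664380, 38545783 and 44249640 for palmitate, and 26110989, 35876350 and 50264695 for palmitate with C3a. Replicate 1 of every group was sequenced in batch 1 and had the lowest total of its group. The insulin genes Ins2 and Ins1 took 8.29% to 11.8% and 3.19% to 5.36% of counts, and the glucagon gene Gcg 2.37% to 3.78%.

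The first comparison, palmitate against vehicle (3 libraries each), asks what the fatty acid did to islets without added C3a. Of the integrated stress response list 25 of 27 genes rose and of the fatty acid oxidation list 19 of 27, while 12 of 24 beta cell identity genes and 8 of 13 endothelial markers fell. Angptl4, a secreted lipase inhibitor induced by fatty acids, rose by 3.38 ± 0.29 on the log2 scale (SE). Cpt1a, which brings long-chain fatty acids into mitochondria, rose by 1.86 ± 0.11, and the lipid droplet protein gene Plin2 by 1.80 ± 0.13. The stress-induced cytokine gene Gdf15 rose by 1.48 ± 0.14, and Glp1r, the receptor for the incretin GLP-1, fell by 0.89 ± 0.07 on the log2 scale.

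Of 15794 genes tested, 4005 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2112 higher and 1893 lower with palmitate. At least a 2-fold change was seen in 258 of these, 155 higher and 103 lower. In 3992 of the 4005 genes, the same-numbered libraries differed in 1 direction in all 3 pairs. Within batch 2 alone (8 libraries of the 4 groups), 2058 genes passed, and 97.6% of them had the same sign in batch 1.

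The gene with the highest fold among those selected was Fbp2 (ENSMUSG00000021456.8, GRCm38 chromosome 13, 62836877 to 62858422, minus strand), which encodes a gluconeogenic fructose bisphosphatase. It had 1.20, 2.78 and 1.90 CPM in the vehicle libraries and 13.9, 25.1 and 25.5 CPM in the palmitate libraries, a log2 change of 3.46 ± 0.15 (edgeR adjusted p = 3.92e-07). Angptl4 (ENSMUSG00000002289.16, chromosome 17, 33773750 to 33781830, minus strand) had an edgeR adjusted p of 3.54e-05. Star (ENSMUSG00000031574.8, chromosome 8, 25806555 to 25815982, plus strand), which moves cholesterol into mitochondria, rose by 3.09 ± 0.22. Others with high folds were the laminin chain gene Lama3 at 3.35 ± 0.43, the small GTPase gene Diras2 at 2.68 ± 0.24, the chloride channel gene Ttyh1 at 2.28 ± 0.12, the neuropeptide precursor gene Vgf at 2.21 ± 0.15 and the neurokinin receptor gene Tacr3 at 2.04 ± 0.23.

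Among genes that fell, Nnat (ENSMUSG00000067786.16, chromosome 2, 157560078 to 157562522, plus strand), an imprinted gene for a small membrane protein, went from 76.6, 55.5 and 59.6 CPM to 8.58, 11.4 and 14.1 CPM, a log2 change of -2.49 ± 0.24 (edgeR adjusted p = 0.000183). Acvr1c (ENSMUSG00000026834.13, chromosome 2, 58267453 to 58357895, minus strand), the activin receptor ALK7, had a log2 change of -1.44 ± 0.11, and the ubiquitin ligase gene Neurl1b -1.44 ± 0.16. The others selected were Cib3 at -1.43 ± 0.29, Tmsb15b2 at -1.37 ± 0.14, the vascular potassium channel gene Kcnj8 at -1.35 ± 0.23 and the matrix gene Aspn at -1.59 ± 0.42. Akap13 also passed (edgeR adjusted p = 0.0352), with 9.39, 8.51 and 6.57 CPM in vehicle and 0.0395, 0 and 0 CPM in palmitate. No fold is given for it, because the palmitate libraries are near 0, the libraries given C3a ran from 0 to 7.21 CPM, and leaving out any of the 6 libraries of the comparison ended its call. The Aspn call ended without vehicle replicate 1 (0.0935) or 3 (0.0588) or palmitate replicate 1 (0.0538), 2 (0.0694) or 3 (0.0625), each an edgeR adjusted p.

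The integrated stress response list was the only list of the 32 tested that passed with both a preset and an estimated correlation in this comparison. Of its 27 measured members, 25 rose, 0 fell and 2 did not pass, and 26 rose when adjusted over the list alone. The median log2 change was 0.70 (limma camera adjusted p = 1.71e-15, and adjusted p = 0.0163 with an estimated correlation). The transcription factor gene Atf4 rose by 0.69 ± 0.06, its target Eif4ebp1 by 1.00 ± 0.08, and Slc3a2, a subunit of amino acid transporters, by 0.36 ± 0.04. In fry, which does not compare a list with other genes, the list's adjusted p was 3.74e-06. The fatty acid oxidation, autophagy, antioxidant, phosphatase, immediate early, ribosomal, ER chaperone, beta cell, endothelial and oxidative phosphorylation lists also passed fry (2.1e-05 to 0.0146). The alpha cell (0.0291) and disallowed lists (0.0446) passed fry but not camera. The heat shock (0.0756), hypoxia (0.0811), interferon-stimulated (0.0811) and proliferation lists (0.156) did not pass fry.

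Fatty acid oxidation genes and targets of the lipid sensor PPAR had 19 of 27 members higher and 1 lower (19 and 2 adjusted over the list alone), with a median of 0.36 (limma camera adjusted p = 1.92e-09, and adjusted p = 0.165 with an estimated correlation). Slc25a20, the mitochondrial acylcarnitine carrier gene, rose by 0.84 ± 0.05 and the acyl-CoA dehydrogenase gene Acadvl by 0.68 ± 0.05 (edgeR). Of the fatty acid synthesis list, 4 of 19 members rose and 4 fell (4 and 5 over the list alone), and its test did not pass (camera adjusted p = 0.824). Dgat2, which makes triglyceride, rose by 1.93 ± 0.26 and Scd1, a desaturase gene, by 0.58 ± 0.09, whereas Mlxipl, the glucose-sensing factor ChREBP, fell by 1.19 ± 0.09 on the log2 scale. Of 24 cholesterol synthesis genes, 6 rose and 3 fell (7 and 3 over the list alone), with no list call (adjusted p = 0.376). Sqle was 0.32 ± 0.05 higher, and Hmgcs1 was lower (edgeR adjusted p = 0.00249).

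ER chaperone and ERAD genes had 14 of 24 members higher and 1 lower (18 and 1 adjusted over the list alone; camera adjusted p = 1.06e-05, and adjusted p = 0.379 with an estimated correlation), with Creld2 at 0.36 ± 0.05 and Dnajb9 at 0.35 ± 0.06. Antioxidant and NRF2 target genes had 12 of 20 higher and 0 lower (16 and 0 over the list alone; camera adjusted p = 6.31e-06, and adjusted p = 0.172 with an estimated correlation). Srxn1, which repairs peroxiredoxins, rose by 0.63 ± 0.06, and Slc7a11, the cystine transporter gene, by 1.20 ± 0.17; the latter also stands in the integrated stress response list. Autophagy and lysosome genes had 12 of 22 higher and 3 lower (12 and 3 over the list alone; camera adjusted p = 0.000663, and adjusted p = 0.206 with an estimated correlation). The autophagy receptor gene Sqstm1 rose by 0.95 ± 0.06 and the cathepsin gene Ctsb by 0.56 ± 0.05. Heat shock genes had 6 of 14 higher and 0 lower (7 and 0 over the list alone; camera adjusted p = 0.00916, and adjusted p = 0.675 with an estimated correlation), led by the co-chaperone gene Bag3 at 0.56 ± 0.08. That list was no longer past the threshold without vehicle replicate 1 (camera adjusted p = 0.0574).

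Of 25 ribosomal protein genes, 23 rose and 0 fell (24 and 0 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 1.37e-11, and adjusted p = 0.372 with an estimated correlation); Rpl3 was 0.48 ± 0.04 higher and Rpl4 0.37 ± 0.04. Of 30 nuclear oxidative phosphorylation genes, 15 rose and 0 fell (21 and 1 over the list alone; camera adjusted p = 6.31e-06, and adjusted p = 0.605 with an estimated correlation), among them Cox5b at 0.41 ± 0.06 and Cyc1 at 0.34 ± 0.05. None of 13 mitochondrially encoded genes passed (0 over the list alone, camera adjusted p = 0.134), with mt-Cytb at -0.25 ± 0.12. That list was lower without palmitate replicate 2 (0.0459) or vehicle replicate 3 (0.0467) with the preset correlation. With all libraries and an estimated correlation its adjusted p was 0.755. Of 24 immediate early and cAMP-responsive genes, 13 rose and 1 fell (17 and 1 over the list alone; camera adjusted p = 2.02e-05, and adjusted p = 0.327 with an estimated correlation). The nuclear receptor genes Nr4a1 and Nr4a2 rose by 1.59 ± 0.20 and 0.91 ± 0.09, and the cAMP-responsive repressor gene Crem by 0.80 ± 0.09. Hypoxia and glycolysis genes had 7 of 22 higher and 0 lower (7 and 0 over the list alone), with a median of 0.70 (camera adjusted p = 0.000123, and adjusted p = 0.675 with an estimated correlation); Ero1l, an ER oxidase gene induced by hypoxia, was 1.05 ± 0.23 higher. The hypoxia genes varied between libraries of 1 group, as given below for vehicle replicate 2.

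Of 24 measured beta cell identity genes, 12 fell and 0 rose (13 and 1 adjusted over the list alone), with a median of -0.20 (camera adjusted p = 0.000201, and adjusted p = 0.486 with an estimated correlation). The zinc transporter gene of insulin granules, Slc30a8, fell by 0.76 ± 0.07 on the log2 scale, the transcription factor gene Pdx1 by 0.52 ± 0.06 and the granule protein gene Sytl4 by 0.53 ± 0.06. The hormone genes did not pass: Ins1 was at -0.14 ± 0.13, Ins2 at -0.10 ± 0.10 and Gcg at 0.01 ± 0.06. Without the libraries numbered 1, Ins1 was at 0.05 and Ins2 at 0.03, so the lower values of both rest on replicate 1. Of 20 disallowed and dedifferentiation genes, 6 rose and 2 fell (6 and 2 over the list alone; camera adjusted p = 0.145), with the lactate transporter gene Slc16a1 1.16 ± 0.15 higher and Nnat among the lower. Of 22 insulin granule and exocytosis genes, 5 rose and 4 fell (8 and 4 over the list alone; camera adjusted p = 0.527), with the granule phosphatase gene Ptprn 0.70 ± 0.06 higher; the list's median of -0.01 and its test, which pointed up, differ in sign.

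Endothelial markers had 8 of 13 lower and 0 higher (10 and 0 adjusted over the list alone), with a median of -0.53 (camera adjusted p = 0.000252, and adjusted p = 0.48 with an estimated correlation); Kdr, a receptor for VEGF, fell by 1.05 ± 0.17 on the log2 scale and Emcn by 1.28 ± 0.22. Of 11 alpha cell markers, 2 rose and 4 fell (2 and 5 over the list alone; camera adjusted p = 0.321), with Gc 0.85 ± 0.08 higher and Slc7a2 at -0.87 ± 0.07. None of 7 delta cell markers passed (0 over the list alone; adjusted p = 0.929), with Sst at 0.16 ± 0.10, a list median of 0.05 and a test that pointed down. Of 5 PP cell markers, 1 rose, Pyy at 0.34 ± 0.08 (1 over the list alone; adjusted p = 0.321). None of 24 acinar markers passed (0 over the list alone, camera adjusted p = 0.323), but the list was higher without vehicle replicate 2 (adjusted p = 0.00133, preset correlation). With all libraries and an estimated correlation the acinar adjusted p was 0.888. Of 10 duct markers, 2 rose and 1 fell (2 and 1 over the list alone; adjusted p = 0.376), with Epcam 0.18 ± 0.04 higher. Of 14 fibroblast and pericyte markers, 0 rose and 3 fell (0 and 1 over the list alone, camera adjusted p = 0.102), with Pdgfrb at -1.02 ± 0.24. Without palmitate replicate 1 (adjusted p = 0.00364) or vehicle replicate 2 (0.039) the list was lower with the preset correlation. With all libraries and an estimated correlation the fibroblast adjusted p was 0.755. Of 15 macrophage markers, the lysosomal Cd68 rose by 0.70 ± 0.09 and the complement gene C1qa fell by 0.56 ± 0.14 on the log2 scale (1 and 1 over the list alone; adjusted p = 0.802). Of 8 Schwann cell markers, 1 fell and 0 rose (1 and 0 over the list alone; adjusted p = 0.26). Only 4 lymphocyte markers were measured, too few for the list test, and the B cell receptor gene Cd79a was lower (edgeR adjusted p = 0.00878).

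Of 25 NF-kB and inflammatory genes, 2 rose and 2 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.59), and the prostaglandin synthase gene Ptgs2 rose by 2.03 ± 0.33. Interferon-stimulated genes had 5 of 22 lower and 0 higher (5 and 0 over the list alone; camera adjusted p = 0.00457, and adjusted p = 0.675 with an estimated correlation), with Ddx58 at -0.31 ± 0.08. Of 26 proapoptotic genes, 3 rose and 2 fell (3 and 2 over the list alone; adjusted p = 0.824), with Bax 0.23 ± 0.06 higher and Bcl2l11, which encodes BIM, at -0.55 ± 0.08. Of 14 antiapoptotic genes, 1 rose and 3 fell (2 and 3 over the list alone; adjusted p = 0.626), and Bcl2l1, which encodes BCL-XL, rose by 0.46 ± 0.06. Proliferation genes had 2 of 25 higher and 4 lower (2 and 4 over the list alone), with the replication genes Pcna and Mcm2 0.45 ± 0.07 and 0.51 ± 0.08 higher and the mitotic cyclin gene Ccnb1 at -0.85 ± 0.24. The proliferation list pointed down (camera adjusted p = 0.0472, and adjusted p = 0.675 with an estimated correlation), and its call ended with the replicate number as a block (adjusted p = 0.052), without vehicle replicate 1 (0.179) and without palmitate replicate 2 (0.121).

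Of 20 complement genes, 1 fell and 0 rose (1 and 0 adjusted over the list alone; camera adjusted p = 0.399), namely Cd59a at -0.37 ± 0.07, a gene for an inhibitor of the membrane attack complex. C3ar1 was at -0.20 ± 0.16 (edgeR adjusted p = 0.411) and C3 at -0.30 ± 0.62 (adjusted p = 0.785, and a log2 change of 0.33 without vehicle replicate 1); Cfd had 2 counts in total and was not tested. Dual-specificity phosphatases, some of which switch off MAP kinases, had 8 of 20 higher and 2 lower (10 and 2 over the list alone). The list's camera adjusted p was 0.0193, and 0.327 with an estimated correlation. Dusp4 was 1.41 ± 0.16 and Dusp5 0.62 ± 0.06 higher. Dusp26 fell by 0.39 ± 0.12 on the log2 scale (edgeR adjusted p = 0.0307), a call that ended on leaving out vehicle replicate 1, 2 or 3 or palmitate replicate 1 or 3. Its most abundant transcript, tested alone, was at 0.084. Dusp26, and with it the phosphatase list, was chosen from memory of published work on these libraries, so neither is independent evidence.

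**Figure D1:**
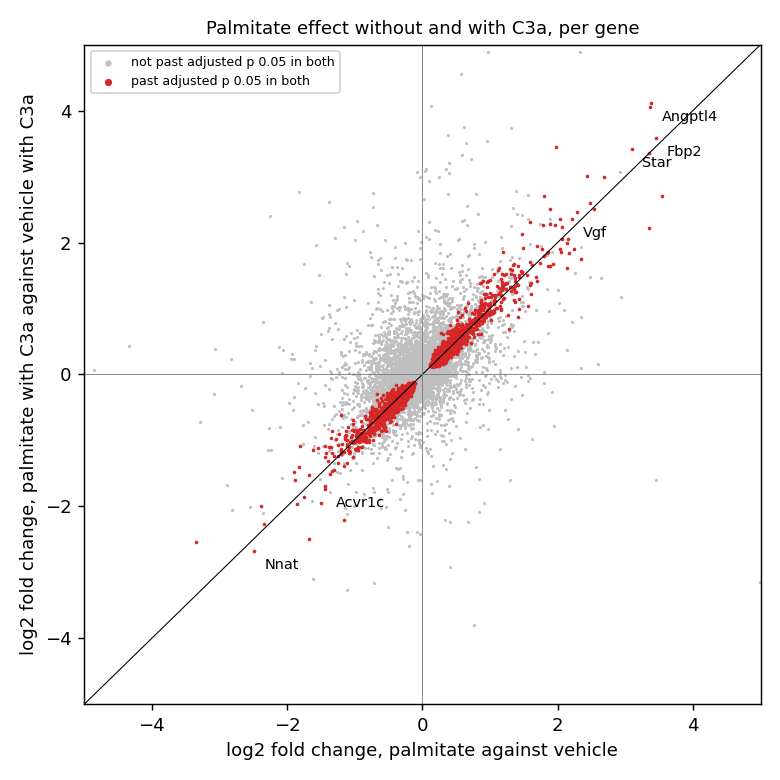
Log2 fold change of each of 15794 genes for palmitate against vehicle without C3a (horizontal axis) and with C3a (vertical axis), 3 libraries per group. Genes that passed in both comparisons, 1744 higher and 1524 lower, lie along the diagonal; 26 genes lie outside the axis limits of 5.

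The comparison of palmitate with C3a against vehicle with C3a (3 libraries each) asks whether islets given C3a responded to palmitate alike. Fbp2 rose by 3.58 ± 0.16 on the log2 scale, Angptl4 by 4.12 ± 0.30, Cpt1a by 1.86 ± 0.11 and Gdf15 by 1.54 ± 0.14, while Nnat fell by 2.68 ± 0.24, Glp1r by 0.89 ± 0.07 and Slc30a8 by 0.81 ± 0.07. The integrated stress response list was again the only one past the threshold with both correlations. Its counts were 25 of 27 higher and 0 lower (25 and 0 adjusted over the list alone). Its camera adjusted p was 1.94e-14, and 0.0201 with an estimated correlation. Of the lists that camera called with the preset correlation, hypoxia (adjusted p = 0.0688), heat shock (0.08) and interferon-stimulated genes (0.15) did not pass fry. The others did (0.044 or less), as did the phosphatase (0.000891) and alpha cell lists (0.0295), which camera did not call.

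In edgeR's test 4246 genes passed, 2175 higher and 2071 lower, of which 318 changed at least 2-fold (217 higher, 101 lower). Within batch 2 alone 2331 passed, with 96.3% at the same sign in batch 1. Genes past the threshold in both palmitate comparisons were 1744 higher in both, where chance gives 291, and 1524 lower in both, where chance gives 248; 0 went opposite ways. A further 737 passed only without C3a and 978 only with it. These are not shown to differ, since no gene passed the test of the difference given below for the interaction. Of the 4005 genes called without C3a, 99.3% had the same sign with it.

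Other genes with high folds were Star at 3.42 ± 0.23, Lama3 at 3.36 ± 0.44, Ttyh1 at 2.46 ± 0.13, Vgf at 2.36 ± 0.15 and Tacr3 at 2.36 ± 0.24. Lower were Acvr1c at -1.73 ± 0.11, Cib3 at -1.69 ± 0.29, the water channel gene Aqp4 at -1.39 ± 0.07, the coenzyme Q kinase gene Coq8a at -1.35 ± 0.10, Togaram2 at -1.25 ± 0.13 and the interferon-induced GTPase gene Gbp2 at -1.47 ± 0.44. The Gbp2 call (edgeR adjusted p = 0.0344) ended without palmitate with C3a replicate 1 (0.123) or 2 (0.112) and without vehicle with C3a replicate 3 (0.117, and a log2 change of -0.87). The receptor gene C3ar1 was at 0.00 ± 0.16 and C3 at 1.61 ± 0.63 (edgeR adjusted p = 0.105), or 0.61 without palmitate with C3a replicate 3. Dusp26 was at -0.35 ± 0.12 (adjusted p = 0.048, a call that ended without replicate 1 or 2 of vehicle with C3a or replicate 1 or 3 of palmitate with C3a, and a log2 change of -0.20 without vehicle with C3a replicate 2). Ins1 was at -0.35 ± 0.13 (0.0671) and Ins2 at -0.27 ± 0.10 (0.0617), or -0.16 and -0.14 without the libraries numbered 1.

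Fatty acid oxidation and PPAR genes had 19 of 27 higher and 1 lower (19 and 1 adjusted over the list alone; camera adjusted p = 1.36e-08, and adjusted p = 0.163 with an estimated correlation), among them Pdk4, a brake on glucose oxidation, at 0.97 ± 0.08. Beta cell identity genes had 14 of 24 lower and 0 higher (16 and 0 over the list alone; adjusted p = 2e-06, and adjusted p = 0.418 with an estimated correlation). Ribosomal protein genes had 23 of 25 higher (24 over the list alone; adjusted p = 1.33e-10, and 0.42 as the adjusted p with an estimated correlation), and antioxidant genes 15 of 20 (16 over the list alone; adjusted p = 4.7e-06, and adjusted p = 0.163 with an estimated correlation). Also higher were ER chaperone genes (12 of 24; camera adjusted p = 0.000288, and adjusted p = 0.484 with an estimated correlation), immediate early genes (13 of 24; 1.58e-05, and adjusted p = 0.31 with an estimated correlation) and oxidative phosphorylation genes (11 of 30; 0.000647, and adjusted p = 0.659 with an estimated correlation). Autophagy genes (11 of 22 higher; 0.00228, and adjusted p = 0.295 with an estimated correlation) and hypoxia genes (11 of 22 higher; 0.00018, and adjusted p = 0.659 with an estimated correlation) followed. Endothelial markers had 5 of 13 lower (6 over the list alone; 0.00172, and adjusted p = 0.53 with an estimated correlation), with the fenestra gene Plvap at -0.99 ± 0.26.

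A further 3 lists passed and depended on single libraries. Heat shock genes were higher (5 of 14; camera adjusted p = 0.0148, and adjusted p = 0.659 with an estimated correlation), except without palmitate with C3a replicate 1 (0.051) or vehicle with C3a replicate 2 (0.092). Interferon-stimulated genes were lower (3 of 22; 0.0235, and adjusted p = 0.659 with an estimated correlation), except without palmitate with C3a replicate 1 (0.113) or vehicle with C3a replicate 3 (0.253). The disallowed gene list was higher (6 of 20; 0.0438, and adjusted p = 0.42 with an estimated correlation), except without replicate 3 of vehicle with C3a (0.0655) or of palmitate with C3a (0.255). The phosphatase list (7 higher, 3 lower; adjusted p = 0.064) and the proliferation list (2 higher, 1 lower; adjusted p = 0.447) did not pass, though the first was higher without palmitate with C3a replicate 3 (0.0377) and the second lower without palmitate with C3a replicate 2 (0.0104). With the preset correlation the acinar list passed upward without vehicle with C3a replicate 2 (0.0462) and the macrophage list upward without palmitate with C3a replicate 1 (0.0235). The Schwann cell list passed downward without palmitate with C3a replicate 2 (0.00391) or vehicle with C3a replicate 3 (0.0328). With all libraries and an estimated correlation the adjusted p was 0.906, 0.906 and 0.659 for these 3 lists. The alpha cell list (1 higher, 5 lower; adjusted p = 0.359) had a median of 0.04 and a test that pointed down.

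The fibroblast and pericyte list did not pass (adjusted p = 0.381), and its median of 0.27 and its test, which pointed down, differ in sign. Replicate 3 of palmitate with C3a stood apart in this list: Col3a1 was at 698 CPM, against 55.6 and 65.0 CPM in replicates 1 and 2, and Lum at 44.7 CPM. Without that library the list was lower with palmitate (camera adjusted p = 0.00232, preset correlation). With all libraries and an estimated correlation its adjusted p was 0.841. Col3a1 was also at 312 CPM in palmitate replicate 1 and 214 CPM in vehicle replicate 1, which were the highest of their groups in the list's mean too. Without palmitate replicate 1 and palmitate with C3a replicate 3 together, a choice made after seeing the data, 3043 genes passed for palmitate against vehicle and 3644 for palmitate with C3a against vehicle with C3a.

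**Figure D2:**
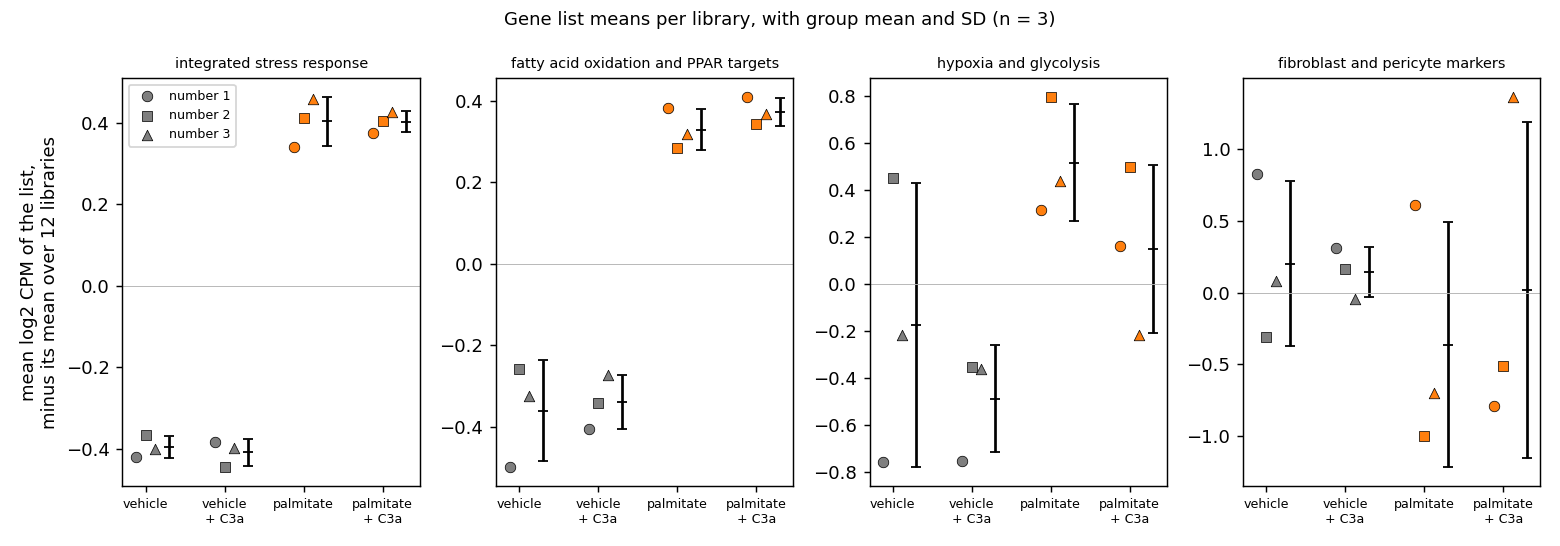
Mean log2 CPM of 4 gene lists in each of the 12 libraries, minus the list's mean over all 12, with 1 symbol per replicate number and bars for the group mean and SD (n = 3). Palmitate libraries lie above 0 for the integrated stress response and fatty acid oxidation lists, vehicle replicate 2 stands at 0.45 in the hypoxia list above the other vehicle libraries, and replicate 3 of palmitate with C3a stands at 1.36 in the fibroblast list.

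**Figure D3:**
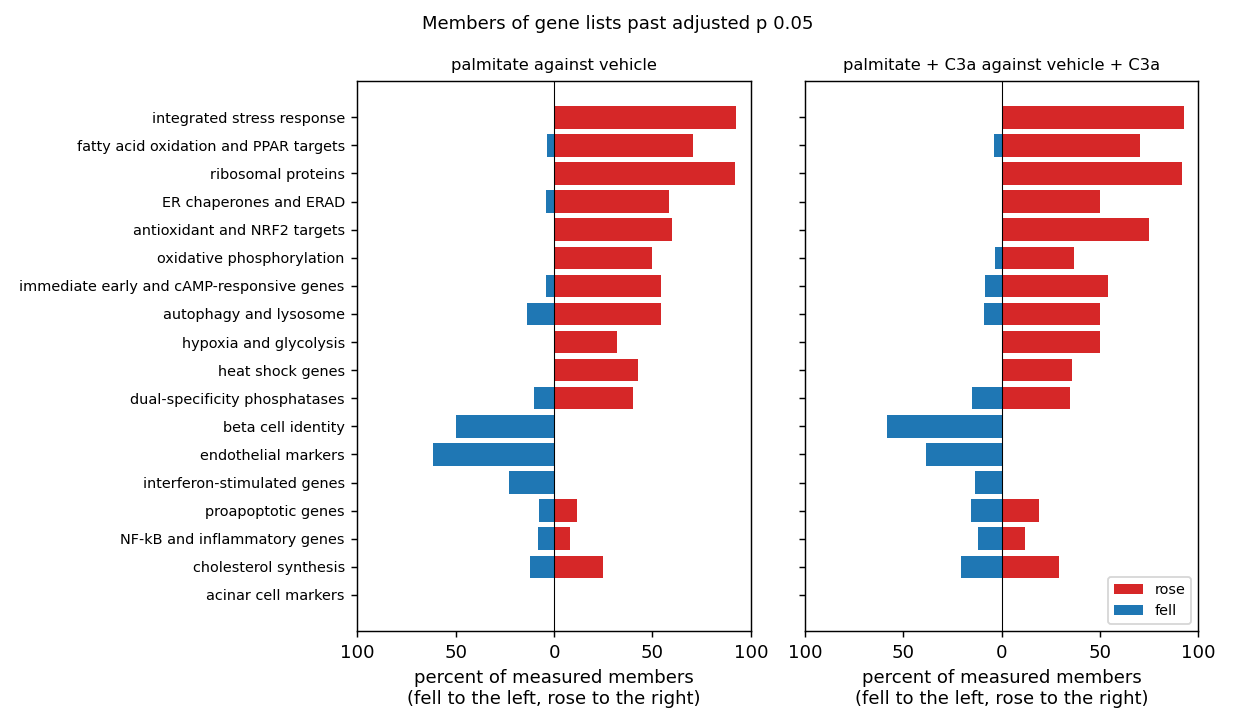
Percent of the measured members of 18 gene lists that passed the edgeR test at an adjusted p of 0.05, to the right for those that rose and to the left for those that fell, for palmitate against vehicle (left panel) and palmitate with C3a against vehicle with C3a (right panel), 3 libraries per group. Of the integrated stress response list 25 of 27 rose in both panels, and of the beta cell identity list 12 and 14 of 24 fell.

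The comparison of palmitate with C3a against palmitate (3 libraries each) asks the question of the series title, what C3a does to stressed islets. C3ar1 was at 0.12 ± 0.16 on the log2 scale, C3 at 1.02 ± 0.61, Dusp26 at -0.01 ± 0.12, Ins1 at -0.08 ± 0.13 and Ins2 at -0.06 ± 0.10. C3 was at 70.4 CPM in replicate 3 of palmitate with C3a, against 17.3 and 20.2 CPM in replicates 1 and 2, and its log2 change was 0.03 without that library. None of the 15794 genes passed in edgeR (smallest adjusted p = 0.595). At an unadjusted p under 0.05 there were 430 genes, where chance gives 790, and DESeq2 called 1, Gm21985, named here after its values were seen. With the replicate number as a block there were 568, and 511, 332 and 766 for C3a in vehicle, the interaction and the average. These too lie under chance, so the lack of a term for the pairing in the main fit does not account for the low counts. With only the groups compared, the counts were 257 for C3a in palmitate and 702 in vehicle. Adding the block to that, a choice made after seeing the data, gave 626 and 991. The counts thus depend on how the spread is estimated, and a count under chance is no evidence that C3a had no effect. Over the 9460 genes with at least 10 CPM, the median half-width of the 95% interval was 0.145 on the log2 scale, and in 99.1% of them the interval excluded a 2-fold change.

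The genes with the smallest unadjusted p, none past the threshold, were the adhesion adaptor gene Sorbs3 at 0.44 ± 0.10, Gprc5b at 0.35 ± 0.09, the receptor phosphatase gene Ptprs at 0.25 ± 0.07 and Rpp14 at 0.18 ± 0.05. On the lower side were the vesicle SNARE gene Vamp7 at -0.24 ± 0.06, Sh3bgrl at -0.21 ± 0.06, Prpf18 at -0.16 ± 0.04 and Mzt1 at -0.15 ± 0.04 (n = 3 per group; edgeR adjusted p = 1 for each). The vasodilator gene Adm, at -2.49 on the log2 scale, was called only without all libraries numbered 1 or without palmitate with C3a replicate 1.

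Although 0 members passed in any list, over all genes or adjusted over the list alone, 5 lists passed limma's camera with the preset correlation. Hypoxia and glycolysis genes were lower as a list (median -0.20, 20 of 22 below 0; adjusted p = 0.000765), but not without palmitate replicate 2 (0.0643) or palmitate with C3a replicate 3 (0.858). Proliferation genes were higher as a list (median 0.16, 20 of 25 above 0; adjusted p = 0.00464), but not without palmitate replicate 2 (0.12) or palmitate with C3a replicate 2 (0.99). The ER chaperone list (median -0.04; 0.0456), the insulin granule list (median -0.04; 0.0376) and the complement list (median 0.19; 0.0456) each lost their call on leaving out palmitate replicate 2 or 3 or palmitate with C3a replicate 3. Without palmitate with C3a replicate 3 their adjusted p was 0.302, 0.526 and 0.858. Replicates 1 and 2 of palmitate with C3a, left out, also ended the ER chaperone call (0.0519 and 0.0787), replicate 1 the insulin granule call (0.0861) and replicate 2 the complement call (0.0518). None of the 5 passed with an estimated correlation (adjusted p = 0.943 for each) or in fry (adjusted p = 0.981 for each), which asks whether a list's genes move on balance 1 way without comparing them with other genes. Fibroblast and macrophage lists did not pass (0.308 each). With the preset correlation they passed upward without palmitate with C3a replicate 1 (4.87e-06 and 2.79e-07) or palmitate replicate 1 (0.0024 and 0.00385). They passed downward without palmitate with C3a replicate 3 (0.0292 and 0.0146). With all libraries and an estimated correlation both had an adjusted p of 0.943.

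A further 7 lists, which did not pass with all libraries, passed camera with the preset correlation in this comparison when 1 was left out. With all libraries their estimated-correlation adjusted p was 0.943 or more, and 0 members passed. Without palmitate with C3a replicate 1, the endothelial (0.0234), NF-kB (0.00409) and disallowed lists (0.0211) passed upward. Without palmitate replicate 1, the disallowed list passed upward (0.0254) and the beta cell identity (0.00385) and mitochondrially encoded lists (0.0116) downward. The oxidative phosphorylation and ribosomal protein lists passed downward without palmitate replicate 2 (6.87e-06 and 2.19e-05), the former also without palmitate with C3a replicate 3 (0.00754). The endothelial list passed upward without palmitate replicate 3 (0.00407).

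The comparison of vehicle with C3a against vehicle (3 libraries each) asks what C3a does to unstressed islets. C3ar1 was at -0.09 ± 0.16 on the log2 scale, C3 at -0.89 ± 0.64 (-0.30 without vehicle replicate 1), Dusp26 at -0.05 ± 0.12, Ins1 at 0.13 ± 0.13, Ins2 at 0.10 ± 0.10 and Gcg at -0.10 ± 0.06. None of the 15794 genes passed in edgeR (smallest adjusted p = 0.551); 347 had an unadjusted p under 0.05, where chance gives 790, and DESeq2 called 2, Gm15542 and Gm21985, named after their values were seen. The interval excluded a 2-fold change in 99% of the genes with at least 10 CPM. Genes with the smallest unadjusted p, none past the threshold, were the potassium channel gene Kcnj12 at 0.33 ± 0.08, the transcriptional regulator gene Cited2 at 0.35 ± 0.09, Rhbdf1 at 0.33 ± 0.09 and Dirc2 at 0.17 ± 0.05. On the lower side were Hsd3b2 at -0.21 ± 0.06, Igfbp3, which binds insulin-like growth factors, at -0.21 ± 0.06, Zfp330 at -0.15 ± 0.04 and Ahnak at -0.32 ± 0.10.

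The hypoxia list was lower as a list with C3a in vehicle (median -0.38, 21 of 22 below 0; camera adjusted p = 3.92e-05), but not without vehicle replicate 2 (0.599). In that library the glucose transporter gene Slc2a1 stood at 62.3 CPM and the lactate dehydrogenase gene Ldha at 90.9 CPM. The list of mitochondrially encoded genes was lower (median -0.14; 0.00435), but not without vehicle replicate 1 (0.604) or vehicle with C3a replicate 1 (0.136) or 3 (0.646). The beta cell identity list was higher (median 0.03; 0.0493), but not with the replicate number as a block (0.0633), without vehicle replicate 2 (0.429) or 3 (0.211), or without vehicle with C3a replicate 1 (0.86) or 2 (0.107). With an estimated correlation the adjusted p was 0.987 for each of these 3 lists, and in fry 0.995. The acinar list, which did not pass (0.114), passed upward without vehicle replicate 2 (5.08e-13) or vehicle with C3a replicate 3 (1.78e-07). The NF-kB list passed upward without vehicle replicate 1 (2.7e-05). Without vehicle with C3a replicate 2, the delta cell (0.0208), interferon-stimulated (0.00166) and oxidative phosphorylation lists (0.0106) passed upward. Without vehicle with C3a replicate 3, the delta cell list passed upward (0.0185) and the interferon-stimulated (0.00191) and heat shock lists (0.0411) downward. These are camera tests with the preset correlation. With all libraries 0 members of these lists passed, and each list had an adjusted p of 0.987 with an estimated correlation.

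The interaction, the C3a effect in palmitate minus the C3a effect in vehicle over all 12 libraries, asks whether C3a acted differently on stressed islets. C3 was at 1.91 ± 0.88 on the log2 scale (0.86 without palmitate with C3a replicate 3), C3ar1 at 0.21 ± 0.23, Dusp26 at 0.04 ± 0.17 and Ins1 at -0.21 ± 0.18. None of the 15794 genes passed in edgeR (251 at an unadjusted p under 0.05, where chance gives 790) and 0 in DESeq2, and the interval excluded a 2-fold difference in 98.3% of genes with at least 10 CPM. With the smallest unadjusted p, none past the threshold, were Igfbp3 at 0.30 ± 0.08, the kinase gene Fyn at 0.28 ± 0.08, Gprc5b at 0.44 ± 0.13 and Rpp14 at 0.24 ± 0.07, and on the lower side DXBay18 at -0.74 ± 0.23, Zbtb8a at -0.49 ± 0.16, the ubiquitin ligase gene Rnf8 at -0.32 ± 0.11 and Pdzd4 at -0.17 ± 0.06. The beta cell identity list (median -0.07), the complement list (median 0.40) and the insulin granule list (median -0.06) passed camera with the preset correlation, each at an adjusted p of 0.0245. None passed with an estimated correlation (adjusted p = 0.972 for each) or in fry (0.976), and 0 members passed. Each call ended without vehicle with C3a replicate 1 (0.546, 0.399 and 0.399) or palmitate replicate 2 (0.308, 0.253 and 0.308). The beta cell call also ended without vehicle replicate 2 (0.106) or 3 (0.0849), palmitate replicate 3 (0.143), vehicle with C3a replicate 2 (0.0603) or palmitate with C3a replicate 1 (0.161). The complement call ended without vehicle replicate 1 (0.283) or palmitate with C3a replicate 3 (0.15), and the insulin granule call without vehicle replicate 3 (0.0616) or palmitate with C3a replicate 3 (0.369). Another 14 lists passed in 32 combinations of a list and 1 library left out.

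C3a averaged over vehicle and palmitate, 6 libraries against 6, gives the narrowest intervals on C3a, with a median half-width of 0.103 on the log2 scale over genes of at least 10 CPM. Gm21985, a predicted gene on chromosome 2 that overlaps Katnbl1, was the only gene past the threshold in edgeR (adjusted p = 0.0306) and was named after its values were seen. It had 197 counts in the libraries without C3a, 19 to 60 in each, and 3 in those with C3a, 0 in 5 of 6. Katnbl1 was at -0.12, and reads shared between overlapping genes make the counts of Gm21985 uncertain. With the replicate number as a block 0 genes passed, DESeq2 called 2 (Gm15542 and Gm21985), and 555 genes had an unadjusted p under 0.05, where chance gives 790. Gm21985 also lost its call without vehicle replicate 1, 2 or 3, palmitate replicate 1, 2 or 3, vehicle with C3a replicate 1 or 2, or palmitate with C3a replicate 2, although its counts lay apart in every library.

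Named genes with the smallest unadjusted p on the average, none past the threshold, were Rhbdf1 at 0.28 ± 0.06, Prr7 at 0.34 ± 0.08, Plekhg2 at 0.27 ± 0.07 and Nfkbil1 at 0.20 ± 0.05. On the lower side were the mevalonate pathway gene Pmvk at -0.17 ± 0.05, Smim15 at -0.16 ± 0.04, Paip2b at -0.09 ± 0.03 and Zfp330 at -0.10 ± 0.03. C3ar1 was at 0.02 ± 0.12. The hypoxia list was lower (median -0.29, 22 of 22 below 0, 0 members past; camera adjusted p = 1.09e-07), with an adjusted p = 0.932 with an estimated correlation and 0.923 in fry. Another 10 lists passed in 19 combinations of a list and 1 library left out.

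Across all 15794 genes, the palmitate effects without and with C3a, which share no library, had a Pearson r of 0.50, where 50 simulations of unchanged groups gave -0.107 to 0.159. The C3a effects in palmitate and in vehicle, which also share no library, had an r of 0.039 (simulated -0.083 to 0.139). The palmitate effect and the C3a effect in palmitate share the palmitate libraries, which pushes r down by itself: r was -0.341, where the simulations averaged -0.505 (range -0.613 to -0.41). The covariance was -0.0548, above the simulated mean of -0.0665 by 0.0117. The variances of the replicate block fit, a choice made after seeing the data, gave a simulated mean of -0.0622. Their range of -0.0743 to -0.0517 holds the observed covariance, so no shared effect is shown. The range of r with these variances, -0.547 to -0.44, does not hold -0.341. The simulated groups had no palmitate effect, which in the real data adds to the spread of the palmitate changes and by itself weakens r. For this pair the simulated ranges of r therefore decide nothing. With no shared library r was -0.028. Over genes of at least 10 CPM by the average of edgeR these 3 values were 0.843, -0.011 and -0.222, and by mean log2 CPM 0.935, 0.23 and -0.189; both filters were chosen after seeing the data. With the first filter the simulations averaged -0.496 for the third pair (range -0.714 to -0.229), and -0.509 with the block variances (range -0.704 to -0.14). Genes are not independent replicates, so r has no p value here.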

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

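The tests of single libraries in the hypoxia and fibroblast lists were chosen only after the results were seen; the tests of transcript length and scaling were written before, but 2 bounds were changed after their values were seen. The first wording excluded a fibroblast response to C3a by any difference below 0 and now asks for more than the SD of the 3, and a swap of scaling methods that shifts the median by under 0.05 now counts as no test.

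In the interaction of palmitate and C3a, 3 lists passed limma's camera with the preset correlation, each at an adjusted p of 0.0245. Beta cell identity (22 of 24 members below 0), insulin granule (16 of 22 below 0) and complement genes (17 of 20 above 0) had adjusted p = 0.972 with an estimated correlation and 0.976 in fry, and none of their members passed. Each call also ended without vehicle with C3a replicate 1 or palmitate replicate 2, so no difference in the C3a effect is shown. Among transcripts outside the annotation used, 822 were tested, and 4 were higher and 2 lower with palmitate than with vehicle in edgeR.

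The hypoxia and glycolysis list was lower with C3a in limma's camera with the preset correlation, but not with an estimated one (adjusted p = 0.943 in palmitate, 0.987 in vehicle and 0.932 on average) or in fry, and 0 members passed. A single control culture apart from the rest may account for it in vehicle: without vehicle replicate 2 the list's camera adjusted p was 0.599 and its median -0.08. The list mean was below 0 in 5 of 6 same-numbered differences, at 0.01, -0.80 and -0.14 in vehicle and -0.15, -0.30 and -0.66 in palmitate (SD 0.319). All 3 were below 0 in palmitate, but the list's call there ended without palmitate replicate 2 (0.0643) or palmitate with C3a replicate 3 (0.858), so an effect of C3a in every culture set and single libraries apart cannot be told apart with 3 differences. In the fit with the replicate block, the hypoxia list's camera adjusted p with the preset correlation was 4.55e-06 in palmitate and 5.72e-08 in vehicle. Fry in that fit gave an adjusted p of 0.996 and 0.987. The design names no oxygen measure, and none was tested.

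Fibroblast genes were high in replicate 3 of palmitate with C3a. The list's median there was 2.05 above the other 2 libraries of the group, while the acinar, duct, endothelial and Schwann medians differed by -0.21, 0.01, 0.33 and -0.46 and the macrophage median by 0.56, which is consistent with stromal tissue carried into that culture. The same-numbered differences, palmitate with C3a minus palmitate, were -1.57, 0.41 and 1.98 for replicates 1, 2 and 3, and the first rests on palmitate replicate 1, which was also high in these genes. Without that library the list passed upward (0.0024) and without replicate 3 of palmitate with C3a downward (0.0292), so a response to C3a stays open. Islets themselves hold fibroblasts and pericytes, so the source of the RNA stays open.

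Ribosomal protein and oxidative phosphorylation genes, which have short transcripts, were higher with palmitate as lists with the preset correlation (23 of 25 and 15 of 30 members past), but not with an estimated one (adjusted p = 0.372 and 0.605). Of 10000 lists matched on transcript length and abundance, 1.16% had a median as high as the ribosomal list (0.28 against a matched mean of 0.20). The genes of a matched list were drawn independently, whereas the ribosomal genes varied together (estimated correlation 0.599). Medians of matched lists therefore spread less than that of such a list, and the share does not decide whether a length trend carries the rise. For oxidative phosphorylation 25.1% of matched lists had a median as high (0.18 against 0.15). Matched genes could include unlisted genes of the same families and, for oxidative phosphorylation, the listed ribosomal genes. The matched means therefore neither show a length trend nor size its part in either rise. RLE in place of TMM shifted the median of all genes by only 0.012, so that swap tests nothing about scaling, which stays open. A response to palmitate also stays open for both lists and was not separated from length for either.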

How the results depend on the processing

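Alternatives chosen only after the results were seen were the replicate block with only the groups compared, the libraries left out in pairs, the 10 CPM floors, the simulation with block variances and the correlation with no shared library. For named genes past the threshold, 4247 gene and setting combinations kept direction and side, 539 kept direction only and 1 reversed. For called lists, 426 kept both and 131 lost their call, any whose direction turned included. In 0 combinations did a called list pass in the opposite direction. Another 89 combinations brought an uncalled named gene and 142 an uncalled list past the threshold in the direction it already had. The reversal was the most abundant transcript of Dusp26 (0.084) for palmitate against vehicle; the cause was not tested. Without the batch term, which leaves batch differences in the error, 1841 genes passed for palmitate against vehicle and 2074 for palmitate with C3a against vehicle with C3a. Tests of single transcripts, which have fewer counts each, gave 1546 and 1832 genes with a transcript past the threshold. Leaving out libraries, which lowers n, gave 2058 to 3751 and 2331 to 3849; the lowest were without all libraries numbered 1. Leaving out palmitate replicate 1 gave 2760 for palmitate against vehicle, and vehicle replicate 1 gave 2855. For palmitate with C3a against palmitate, DESeq2 called 1 gene, and leaving out libraries gave 0 to 1 (Adm, without replicate 1). For vehicle with C3a against vehicle, DESeq2 called 2, no filter 3 (Igkv12-89, Ighv1-55 and Gm21985), only the groups compared 2 (Gm15501 and Gm21985), and the replicate block with only the groups compared 7. The 1 gene of the C3a average became 0 with the stricter filter, the replicate block, no batch term, the acinar score, the fibroblast-rich pair left out, the hypoxia pair left out and single transcripts; DESeq2 gave 2 and leaving out libraries 0 to 2. The cause of these was not tested, except that the stricter filter removes Gm21985. With an estimated correlation the lists past the threshold numbered 1 in each palmitate comparison and 0 in the others, and with fry 0 in palmitate with C3a against palmitate, in vehicle with C3a against vehicle, in the interaction and in the average. RLE factors gave 5 lists in the interaction. Leaving out libraries gave 2 to 10 lists for palmitate with C3a against palmitate, 1 to 7 for vehicle with C3a against vehicle, 0 to 8 for the interaction and 1 to 8 for the average. The correlation of the palmitate effects was 0.781 with the stricter filter, 0.843 and 0.935 with floors of 10 CPM by average and by mean log2 CPM, and 0.322 to 0.49 without each number. That of the C3a effects was 0.23 with the mean log2 floor, which leaves out 68 genes that the other keeps, and -0.073 to 0.092 without each number. That of palmitate with C3a in palmitate was -0.222 and -0.189 with the floors, -0.028 with no shared library and -0.417 to -0.34 without each number. With the replicate block, 4 named genes lost their call (Cspg4 and Rgs5 without C3a, Pdgfrb and Acta2 with it) and 4 gained one (mt-Nd5 and Serping1 without C3a, Cd14 and Usp18 with it), the proliferation list (0.052) and the beta cell list in vehicle (0.0633) lost theirs, the delta cell list in vehicle (0.0418) and the oxidative phosphorylation list in the interaction (0.0385) gained one, and no gene count other than that of the average moved by over 1.5 times. The median half-width of the 95% interval for palmitate against vehicle was 0.209 over all genes and 0.145 over genes of at least 10 CPM; counts were not thinned, so what depth limits was not tested.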

Other observations

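The list of cytosolic aminoacyl-tRNA synthetases was chosen and tested only after the results were seen; the tests on other splits of the libraries were planned.

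The enzymes that load amino acids onto transfer RNAs include known targets of ATF4. A candidate explanation for the integrated stress response list, that this pathway was active as a whole, predicts that they rise too; the lists share no gene. Of 20 synthetase genes, 18 rose and 0 fell with palmitate against vehicle (median 0.40; limma camera adjusted p = 3.32e-13, and adjusted p = 0.0354 with an estimated correlation). With C3a in both groups 18 also rose (median 0.36; adjusted p = 6.86e-12, and adjusted p = 0.0474 with an estimated correlation). None passed for C3a in palmitate or in vehicle. This is consistent with the hypothesis, which was formed and tested on the same libraries.

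Other splits of the libraries were refitted. The 10 splits of each pair of groups are too few for a share under 0.05. For palmitate against vehicle the real split called 4005 genes and the highest other split 0, and for palmitate with C3a against vehicle with C3a 4246 and 0, so 1 of 10 splits reached the real count in each. For palmitate with C3a against palmitate the real split called 0 and the highest other 0, and for vehicle with C3a against vehicle 0 and 6; any split reaches a count of 0, so that 10 of 10 did says nothing. Of the 10 splits, 4 part all 3 same-numbered pairs, the real one among them, and the others of these gave 0 genes in both palmitate comparisons and in palmitate with C3a against palmitate, and 0 to 2 in vehicle with C3a against vehicle. For the interaction the real count was also 0, so that 100 of 100 drawn splits reached it says nothing about chance. The highest other split gave 517 genes. Its contrast set all libraries numbered 2 against those numbered 3, except vehicle replicate 3, and the fit has no term for these numbers. Drawn splits that fully part numbers 2 and 3 called 0 genes in the interaction but had 1311 to 2505 at an unadjusted edgeR p under 0.05. The 517-gene split had 3027 and the real split 251. The 18 other drawn splits that part all 6 same-numbered pairs called at most 1. Within palmitate the 517-gene split set replicates 1 and 3 and palmitate with C3a replicate 3 against the rest. Yet 10 other drawn splits with that division gave 0 to 1 genes, so it alone does not account for the count. A difference between numbers was not tested apart. For the C3a average 11 of 100 drawn splits of 200 reached the real count of 1 (highest other 4), so chance is not excluded. Swapping the C3a label within palmitate turns the interaction into the average. The highest of 4 thus depends on the draw, since the undrawn partner of the 517-gene split would give that count on the average. Of the drawn splits, 19 part all 6 same-numbered pairs, and the real split was the only 1 of them to call a gene on the average. These 19 splits are too few for a share under 0.05.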
